A study of Rattus norvegicus with 9 samples.

How the data were processed

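Poly(A) RNA of liver from 9 male Wistar rats, an outbred laboratory strain, was sequenced, and every library came from a different animal according to the series design. The labels put 5 animals of 6 months in the young group and 4 animals of 24 months in the old group. Per the labels' protocols, RNA was purified with a Qiagen RNeasy kit and libraries were made with an Illumina TruSeq RNA kit, which does not mark the strand of a transcript. Reads from overlapping genes on opposite strands therefore could not be told apart.

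The authors deposited raw read counts per gene symbol, as whole numbers with no normalization, for 23479 symbols in the 9 libraries. Per the submitters' processing notes the reads were aligned with BWA. Its version, the genome build, the annotation, the counting tool and the treatment of reads that match several genes were not given in the sources used here. Gene families with near-identical members are therefore called uncertain where they are named. The deposited symbols are in capitals, and 16431 of them were matched to the RefSeq annotation of the GRCr8 assembly, which was used for the spelling of symbols only. No coordinates were taken from it.

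Total counts ran from 18942191 to 25215805 in the young libraries and from 18586798 to 32882704 in the old ones. A gene with no count in a library lay under 3 counts, which equals 0.106 to 0.173 CPM (counts scaled to a common library size) depending on the library. Intervals and this floor cover counting error only, since reads without molecular identifiers are not independent molecules. In old 1 all deposited counts were even, and the column was used as deposited, with its halved values as an alternative.

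Genes were kept with edgeR's filterByExpr at its standard settings (minimum count 10, minimum total count 15), which left 12778 of the 18071 genes that had any count. Libraries were scaled with TMM factors, a quasi-likelihood model with robust dispersion was fitted over all 9 libraries, and old was compared with young by edgeR's quasi-likelihood F test, which is two-sided. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with 0.05 as the threshold. Fold changes are old over young on edgeR's fitted scale. CPM values use the TMM-scaled library sizes, and their spread is the SD over the animals of a group. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

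Gene lists for liver pathways, zonation and cell types were fixed in advance, and the 46 lists with at least 3 tested members were compared with all other genes by limma's camera on log CPM (prior count 2). Camera was run with a preset correlation between genes of 0.01, and p-values were adjusted over the 46 lists. It was repeated with an estimated correlation, and limma's fry tested each list without reference to other genes. For the lists past the threshold, and for some others, the members past it are given over all genes tested and adjusted over the list alone. The 13 mitochondrially encoded transcripts had no entry in the table used here, and the exocrine pancreas markers had 2 tested members, so neither list was tested.

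The spread between animals was measured as the median over genes of the log2 ratio of the variance among old to the variance among young libraries, over genes with a mean of at least 10 CPM. Its p-value came from a two-sided permutation test over all 126 splits of the 9 libraries, after each gene was centred on its group means. Values centred in this way are not fully exchangeable between groups, so this p-value is approximate. Library total, share of counts in the 10 most abundant genes and number of genes with a count were compared by exact two-sided permutation tests over the same 126 splits, with Benjamini-Hochberg adjustment over these measures.

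The genes named here follow a rule. It takes the 8 largest rises and the 8 largest falls among genes past the threshold that had a mean of at least 1 CPM in the higher group and no overlap between the groups, leaving out placeholder symbols. It adds up to 2 passing members of each list with the smallest p, or 3 where at least 10 passed, and 10 genes fixed whatever their result. This gave 43 genes, 33 of them past the threshold. The results of 2 of these genes are not reported here. Further genes named as examples were chosen after their values were seen.

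Before the data were examined, the tests, the lists, this rule and these alternatives were set: median-ratio, upper-quartile and totals-only scaling, TMM without the 10 most abundant genes, other low-count filters, DESeq2, limma-voom with and without quality weights, a block for the replicate number, and leaving out each library in turn. Chosen after seeing the data were old 1 halved, the fits without old 3 and 4 together, without young 2 to 5 together and without 25 heart marker genes, and the list tests under totals-only and upper-quartile scaling. The labels give no sequencing batch.

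The steps were tested on simulated counts with known changes before use. Over 12610 simulated genes, 62% of 100 genes changed 2-fold and 92.8% of 97 genes changed 4-fold were recovered, and 13 of 169 called genes (7.69%) were false. With no simulated change 0 genes were called. In these simulations of changes each gene was drawn independently of the others, with the same dispersion in both groups. In the real libraries the variance among old animals was 2.45 times that among young animals at the median gene. These rates therefore need not hold for the real libraries. A simulated variance ratio of 4 was estimated as 3.59 over 7075 genes, and a ratio of 1 as 0.942 over 7166 genes.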

Results

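Liver transcripts of 9 male Wistar rats were counted, 5 aged 6 months (young 1 to 5) and 4 aged 24 months (old 1 to 4), to ask how gene expression in the liver differs between these ages. The libraries held 24885720, 25215805, 19754382, 19574108 and 18942191 counts in young 1 to 5, and 32882704, 18586798, 23327482 and 24550012 counts in old 1 to 4. All counts of old 1 were even, with 0 odd values against 8112 to 8350 in each other library. The first principal component, with 33.5% of the variance, placed all young libraries at -12.7 or below and all old libraries at 14.6 or above.

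Old livers held more transcript of 84 genes and less of 44, and these genes have very different known roles. Rtp4, an interferon-induced gene, rose 3.37-fold, from 14.6 ± 2.12 CPM in 5 young animals to 49.3 ± 6.60 CPM in 4 old animals (mean ± SD). Cish, a feedback inhibitor of cytokine and growth hormone signalling, rose from 1.03 ± 0.476 to 13.4 ± 7.52 CPM. The glucose-producing enzymes Pc and G6pc fell, Pc from 492 ± 30.6 to 301 ± 34.3 CPM and G6pc from 1185 ± 124 to 537 ± 196 CPM. When each library was left out in turn, Pc lost its call in 4 of 9 fits and G6pc in 8 of 9.

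By edgeR's quasi-likelihood test, 84 genes were higher and 44 were lower in old livers, 128 of 12778 (1.00%), and 89 of them differed at least 2-fold (63 higher, 26 lower). An unadjusted p under 0.05 was found for 2031 genes (15.9%), where 639 would come by chance. The groups did not overlap for 834 genes (6.53%, against 1.59% by chance). With library totals as the only scaling, which put the median log2 fold change of all genes at -0.17, the split was 72 higher and 208 lower, so that 25.7% of calls were higher against 65.6% with TMM. The counts of higher and lower genes were 51 and 48 without young 1, 23 and 12 without young 2, 22 and 12 without young 3, 20 and 10 without young 4, and 27 and 12 without young 5. They were 42 and 18 without old 1, 115 and 86 without old 2, 62 and 32 without old 3, and 69 and 21 without old 4. Heart muscle transcripts, summed over 25 markers, made up 129 to 161 CPM of the library total in young 2 to 5 and 4.67 to 6.11 CPM in young 1 and the old libraries. With young 1 alone against the 4 old libraries, edgeR called 0 genes and 429 had an unadjusted p under 0.05; young 1 was then assumed to vary like the old libraries, and no other tool was run there. DESeq2 on all 9 libraries called 386 higher and 269 lower, and limma-voom 35 and 26.

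Of the 33 named genes past the threshold, 9 stayed past it whichever library was left out, among them Ces2e, Tex13b, Slc14a1, Cish, Scrn1, Akr1c12l1, Bhlhb9 and Rtp4. The other 24 lost their call in 1 or more of these fits. G6pc, Alb, Cd36, Ctsh, Egfl7 and Cd79b lost it in 8 of 9 fits. Alas2, Isg15, Aqp1, Sult2a6, RT1-CE10, Cyp2b2 and Cd46 lost it in 7 of 9. Where a highest adjusted p is given with a gene, it comes from 1 of these fits only. The carboxylesterase gene Ces2e, whose counts are uncertain because of close paralogs, had the largest rise, with a log2 fold change of 6.03 ± 0.74 (SE, edgeR adjusted p = 0.00855). It lay at 2.59 ± 1.16 CPM in young and 170 ± 184 CPM in old livers, and 443 CPM in old 4. Tex13b rose by 3.96 ± 0.26 (adjusted p = 0.000169), with 0.519 ± 0.204 against 8.19 ± 0.725 CPM. Slc14a1, a urea transporter, rose by 3.86 (adjusted p = 0.00829), from 0.164 ± 0.0648 to 2.48 ± 1.42 CPM, with young values near the floor of 3 counts. Cish rose by 3.67 (adjusted p = 0.00829). The log2 change of Rtp4 was 1.75 ± 0.13 (adjusted p = 0.000278). Scrn1 fell by 5.64 on the log2 scale, the aldo-keto reductase Akr1c12l1, also uncertain because of paralogs, fell by 5.46, and Bhlhb9 fell by 1.96 (adjusted p = 0.00829 each).

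**Figure D1:**
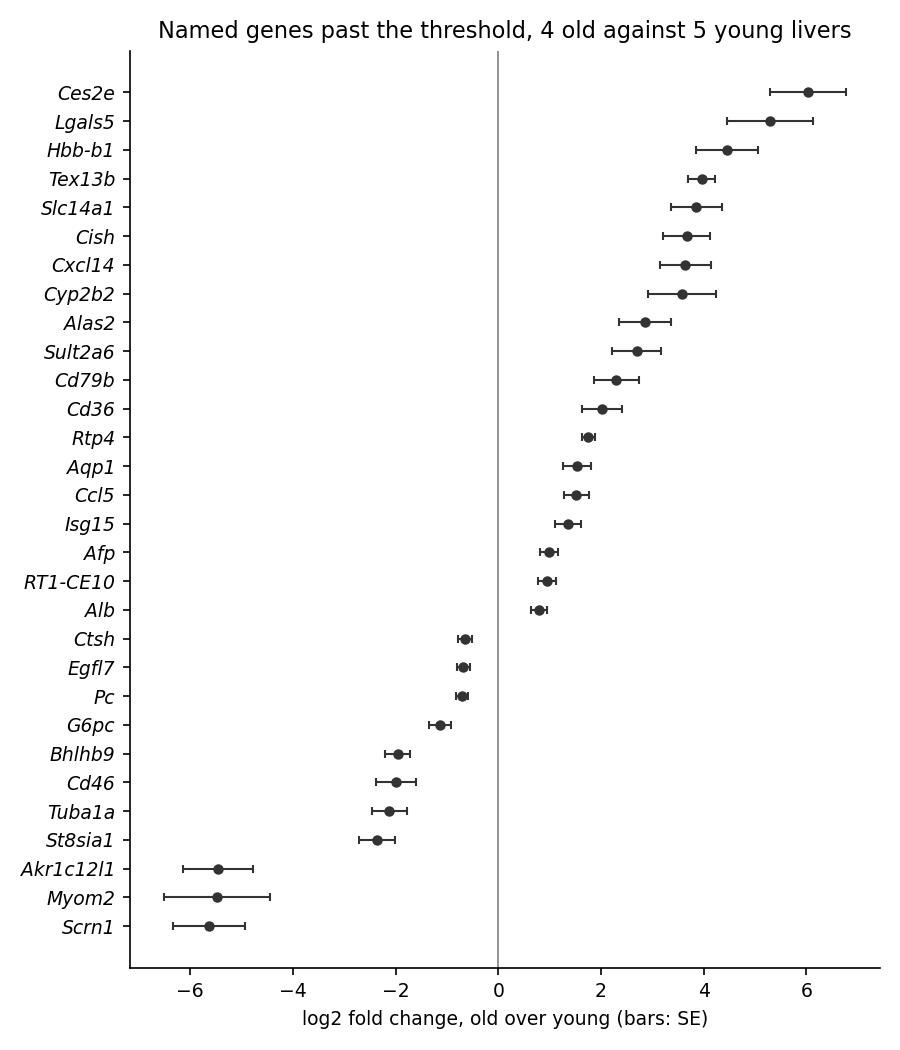
Log2 fold change of old over young (x axis) for genes past the threshold, each with its standard error from edgeR, for 5 young and 4 old livers. Shown are the genes given by the naming rule and reported here, except Mb. Genes named only as further examples are not shown. Among the genes shown, Ces2e lies highest at 6.03 and Scrn1 lowest at -5.64.

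A further 3 large rises each lost their call without at least 1 library. Lgals5 rose by 5.29 (adjusted p = 0.0261, highest 0.0849 without young 4). It rose from 0.127 ± 0.124 to 5.02 ± 4.00 CPM, with young values near the floor of 3 counts. The chemokine gene Cxcl14 rose by 3.64 (adjusted p = 0.0146, highest 0.0547 without young 2). The inducible P450 gene Cyp2b2, uncertain because of paralogs, rose by 3.58 (adjusted p = 0.0423, highest 0.116 without young 2). Among the falls, the ganglioside synthase gene St8sia1 changed by -2.36 (adjusted p = 0.0189; highest 0.0563, without young 3), the tubulin gene Tuba1a by -2.12 (0.0269; 0.0732, without young 4) and the complement regulator gene Cd46 by -1.98 (0.0448; 0.105, without young 5). Mb and Myom2, both muscle genes, were also called lower, but young 1 lay near the old libraries for both. Mb, which encodes myoglobin, had 2 counts in old 1 and 0 in the other old libraries (adjusted p = 0.0391), with 3 counts (0.114 CPM) in young 1 and 6.65 to 9.77 CPM in young 2 to 5, and Myom2 had a log2 fold change of -5.48 (adjusted p = 0.0437), with 0.191 CPM in young 1 and at least 4.06 CPM in young 2 to 5. Without old 1 the adjusted p was 0.155 for Mb and 0.104 for Myom2.

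Markers of lymphocytes were higher in old livers as groups. The 11 natural killer and cytotoxic markers rose with a median log2 fold change of 1.22, the 14 T cell markers with 0.95 and the 7 B cell markers with 0.79 (limma camera adjusted p = 7.71e-08, 3.34e-07 and 7.25e-05). With an estimated correlation the adjusted p was 0.217 for each of these lists. Before the low-count filter the lists held 21, 25 and 18 markers. With genes of a mean of at least 1 CPM only, 5 natural killer, 6 T cell and 3 B cell markers were left. Their camera adjusted p was then 0.000111, 0.0260 and 0.0499, with medians of 1.28, 0.72 and 0.80. Of the natural killer markers 1 passed over all genes, and 8 were higher when adjusted over the list alone. The passing member was Ccl5, a chemokine made by T and natural killer cells, which rose from 3.35 ± 0.874 to 9.65 ± 2.75 CPM (adjusted p = 0.0261; highest 0.0777, without young 4). The granzyme gene Gzmm lay at 0.464 ± 0.196 and 1.38 ± 0.315 CPM. Of the T cell markers 0 passed edgeR's test over all genes, with 9 at an unadjusted p under 0.05 and 3 past by DESeq2, and 9 were higher when adjusted over the list alone. Cd8a lay at 1.27 ± 0.338 and 2.69 ± 1.10 CPM and Lat at 0.541 ± 0.117 and 1.22 ± 0.167 CPM, while Cd3e reached 16.5 CPM in old 3 against at most 1.62 CPM elsewhere. Of the B cell markers 1 passed and 4 were higher when adjusted over the list alone. Cd79b, part of the B cell receptor, rose by 2.30 (adjusted p = 0.0437, highest 0.107 without young 4). It rose from 0.133 ± 0.0819 to 0.699 ± 0.213 CPM, with young values near the floor of 3 counts. Without old 3 and old 4 together the B cell list had an adjusted p of 0.0743.

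Red cell genes rose as well. The 7 erythroid markers had a median log2 fold change of 2.71 (camera adjusted p = 8.33e-07; adjusted p = 0.404 with an estimated correlation), with 3 members past the threshold and 6 higher when adjusted over the list alone. The beta-globin genes Hbb-b1 and Hbb, which are near-identical copies and so uncertain, rose by 4.45 (adjusted p = 0.0146; highest 0.0607, without young 3) and 2.71 (adjusted p = 0.0498; highest 0.122, without young 2). Alas2, the erythroid enzyme of haem synthesis, rose by 2.85, from 3.53 ± 1.83 to 25.6 ± 16.7 CPM (adjusted p = 0.0404; highest 0.111, without young 2).

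Myeloid genes stood apart in old 3. The 10 monocyte and neutrophil markers rose with a median of 1.87 (camera adjusted p = 0.00111; adjusted p = 0.58 with an estimated correlation), with 0 past edgeR's test over all genes (7 at an unadjusted p under 0.05, 3 past by DESeq2) and 7 higher when adjusted over the list alone. The median was 0.56 without old 3 (adjusted p = 0.0227) and the adjusted p was 0.35 without old 3 and old 4 together. S100a9, a neutrophil calcium-binding protein gene, reached 76.1 CPM in old 3 and at most 3.53 CPM in the other libraries. The 20 Kupffer cell and macrophage markers rose with a median of 0.77. Of these 0 passed by edgeR, DESeq2 or adjusted over the list alone, and 6 had an unadjusted p under 0.05 (camera adjusted p = 0.00567; adjusted p = 0.72 with an estimated correlation). Without old 3 this list was not past the threshold, at a median of 0.24 and an adjusted p of 0.402. The macrophage receptor gene Marco lay at 95.7 CPM in old 3, 38.5 in old 4, 31.2 in old 2 and 1.98 in old 1, against 4.81 to 17.1 CPM in the young libraries.

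**Figure D2:**
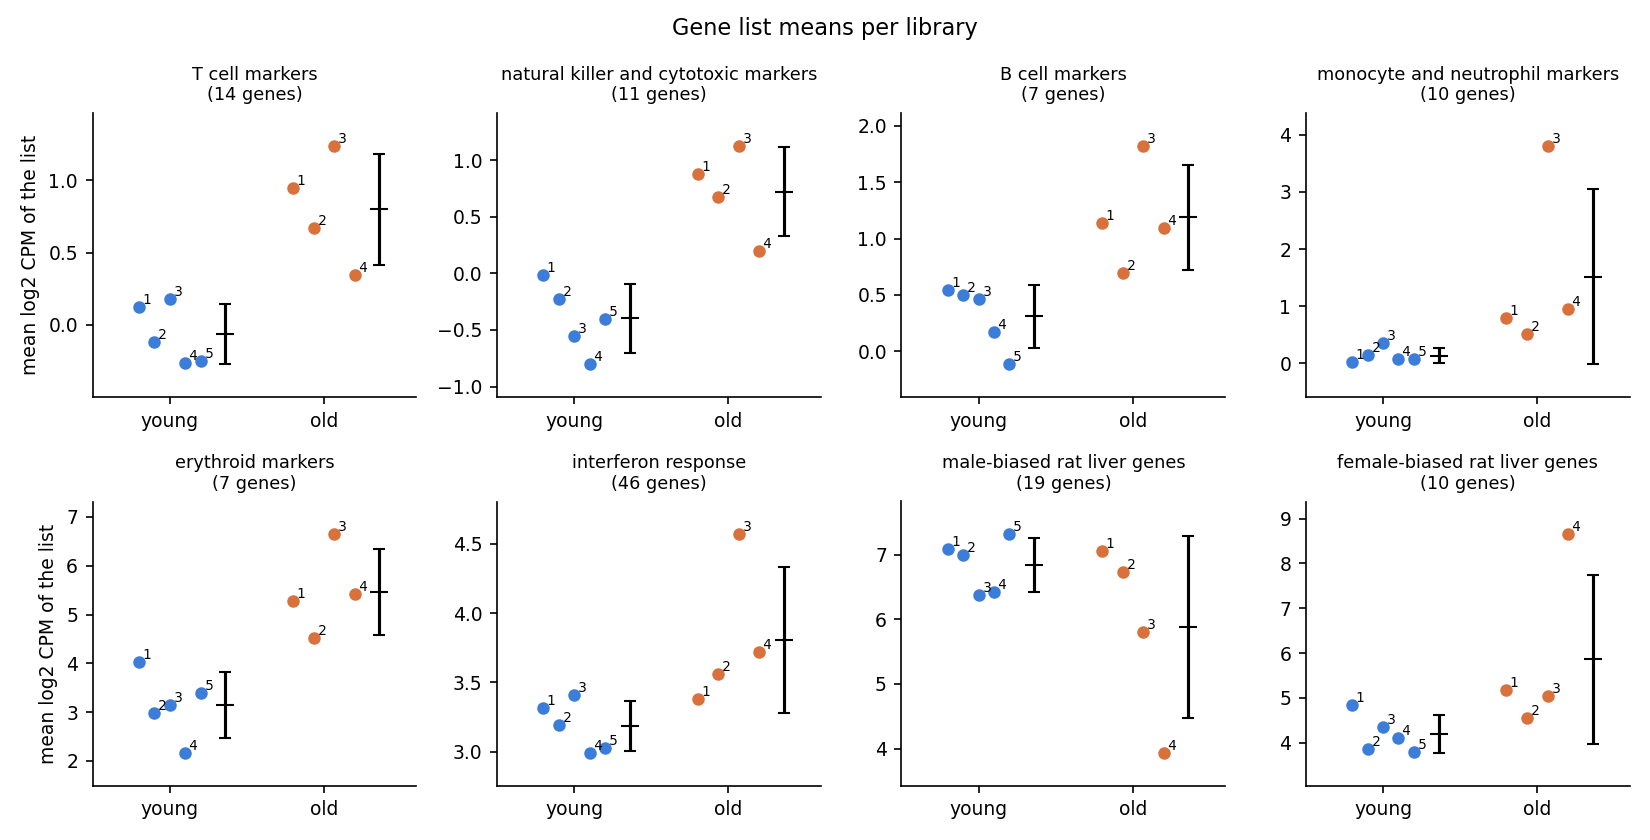
Mean log2 CPM of the members of 8 gene lists (y axis) in each of the 5 young and 4 old libraries, with the black bar at the group mean ± SD and small numbers for the replicate. Old 4 stands at 8.65 for the female-biased genes and old 3 at 3.81 for the monocyte and neutrophil markers, each above all other libraries.

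Interferon and antigen presentation genes were higher in old livers. The 46 interferon response genes rose with a median of 0.62 (camera adjusted p = 7.71e-08; adjusted p = 0.58 with an estimated correlation), with 3 past the threshold, and 18 higher and 1 lower when adjusted over the list alone. Beside Rtp4 these were Isg15, a ubiquitin-like modifier, which rose by 1.35 (adjusted p = 0.0422; highest 0.113, without young 2), and Oas1b, of the family of antiviral oligoadenylate synthases, which rose by 1.06 (adjusted p = 0.0451; highest 0.119, without young 2). Without old 3 the list's median was 0.24 (adjusted p = 0.000274). The 27 genes of MHC class I and antigen processing rose with a median of 0.20 (adjusted p = 0.00659; adjusted p = 0.58 with an estimated correlation), with 1 member past the threshold and 3 higher when adjusted over the list alone. With totals-only scaling the median was 0.02 (adjusted p = 0.00671). The passing member was RT1-CE10, uncertain within its gene family, which rose by 0.94 (adjusted p = 0.0405; highest 0.109, without young 2). Without old 3 the class I list was no longer past the threshold (adjusted p = 0.111). The 9 MHC class II genes rose with a median of 0.48, with 0 past by edgeR, at an unadjusted p under 0.05, by DESeq2 or adjusted over the list alone (camera adjusted p = 0.0290; adjusted p = 0.716 with an estimated correlation). That call ended without young 2 (adjusted p = 0.0886), young 5 (0.138), old 3 (0.312, median 0.12) and old 4 (0.0763), and with genes of a mean of at least 1 CPM only (0.139), and the median was 0.72 without young 3. Cd74, the invariant chain of class II molecules, lay at 43.0 to 142 CPM in young and 62.8 to 182 CPM in old livers (adjusted p = 0.495).

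Secreted liver proteins and inflammatory mediators also rose as lists. The 40 complement and coagulation genes had a median of 0.22 (camera adjusted p = 7.39e-06; adjusted p = 0.217 with an estimated correlation), with 0 past by edgeR over all genes (17 at an unadjusted p under 0.05, 11 past by DESeq2) and 8 higher when adjusted over the list alone. The coagulation factor gene F7 lay at 55.0 ± 1.57 and 80.5 ± 14.4 CPM, and Cfi, a complement protease gene, at 1249 ± 106 and 1695 ± 144 CPM. The 29 acute phase genes had a median of 0.24, with 0 past by edgeR over all genes, 7 at an unadjusted p under 0.05, 4 past by DESeq2 and 2 higher when adjusted over the list alone (adjusted p = 0.00567; adjusted p = 0.58 with an estimated correlation), and without old 3 their adjusted p was 0.0672 at a median of 0.13. The 26 cytokines and NF-kB targets had a median of 0.29, with 2 members past, Cxcl14 and Ccl5, and 7 higher and 1 lower when adjusted over the list alone (adjusted p = 0.0133; adjusted p = 0.58 with an estimated correlation). Without old 3 the adjusted p of that list was 0.259. Among 19 hepatocyte markers the median was 0.22, with 1 past and 3 higher when adjusted over the list alone (adjusted p = 0.00570; adjusted p = 0.58 with an estimated correlation), and without old 1 their adjusted p was 0.0990 at a median of 0.11. The passing marker was Alb, for serum albumin, which rose from 106266 ± 3059 to 184595 ± 37617 CPM (log2 0.80, adjusted p = 0.0423; highest 0.116, without young 2). With totals-only scaling the medians were smaller, at 0.04 for complement and coagulation, 0.06 for acute phase, 0.13 for cytokine and 0.05 for hepatocyte genes, and each list was past the threshold of camera (adjusted p = 0.000185, 0.00191, 0.000175 and 0.0157). Camera compares a list with all other genes, and the median of all genes was -0.17 under this scaling. These calls therefore mean higher relative to the other genes, and do not show a rise of the lists by themselves.

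The 68 ribosomal protein genes rose by a small amount together. Their median was 0.30 and 66 were above 0 (camera adjusted p = 2.26e-09; adjusted p = 0.58 with an estimated correlation). By edgeR 0 passed over all genes, with 17 at an unadjusted p under 0.05 and 2 past by DESeq2, and 1 was higher when adjusted over the list alone. Without old 1, the library of even counts, the median was 0.13 (adjusted p = 3.02e-05), and with totals-only scaling it was 0.11 (adjusted p = 3.06e-10). The 30 genes of the unfolded protein response had a median of 0.13 with TMM and -0.05 with totals-only scaling, with 0 past by edgeR or adjusted over the list alone, 7 at an unadjusted p under 0.05 and 2 past by DESeq2 (camera adjusted p = 0.0428; adjusted p = 0.58 with an estimated correlation). That call ended without young 2 (adjusted p = 0.0674), young 4 (0.0672), young 5 (0.139), old 3 (0.16) or old 4 (0.0833), and with totals-only (0.0799) or upper-quartile scaling (0.0561).

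Sex-biased liver genes moved together, and most in old 4. In male rats the hepatic P450 genes Cyp2c11 and Cyp2c13 are normally high and Cyp2c12 is low. The 10 female-biased genes rose with a median log2 fold change of 2.59 (camera adjusted p = 0.00228; adjusted p = 0.58 with an estimated correlation), with 1 past the threshold and 6 higher when adjusted over the list alone. The 19 male-biased genes fell with a median of -0.87, with 0 past by edgeR or adjusted over the list alone, 4 at an unadjusted p under 0.05 and 2 past by DESeq2 (camera adjusted p = 6.23e-05; adjusted p = 0.58 with an estimated correlation). Cyp2c12 lay at 2054 CPM in old 4 and at 6.14 to 60.9 CPM in the other libraries, while Cyp2c11 lay at 130 CPM in old 4, 590 in old 3 and 1493 to 2254 in the others (adjusted p = 0.494 for Cyp2c11). Without old 4 the medians were 0.74 for the female-biased genes (adjusted p = 0.0451) and -0.50 for the male-biased genes (adjusted p = 0.0128), and without old 3 and old 4 together neither list was past the threshold (adjusted p = 0.121 and 0.39). The sulfotransferase gene Sult2a6, uncertain because of paralogs, was the passing female-biased gene and rose from 65.7 ± 27.6 to 424 ± 307 CPM (adjusted p = 0.0404; highest 0.107, without young 4). The P450 genes of these lists share close paralogs and are uncertain as single genes.

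**Figure D3:**
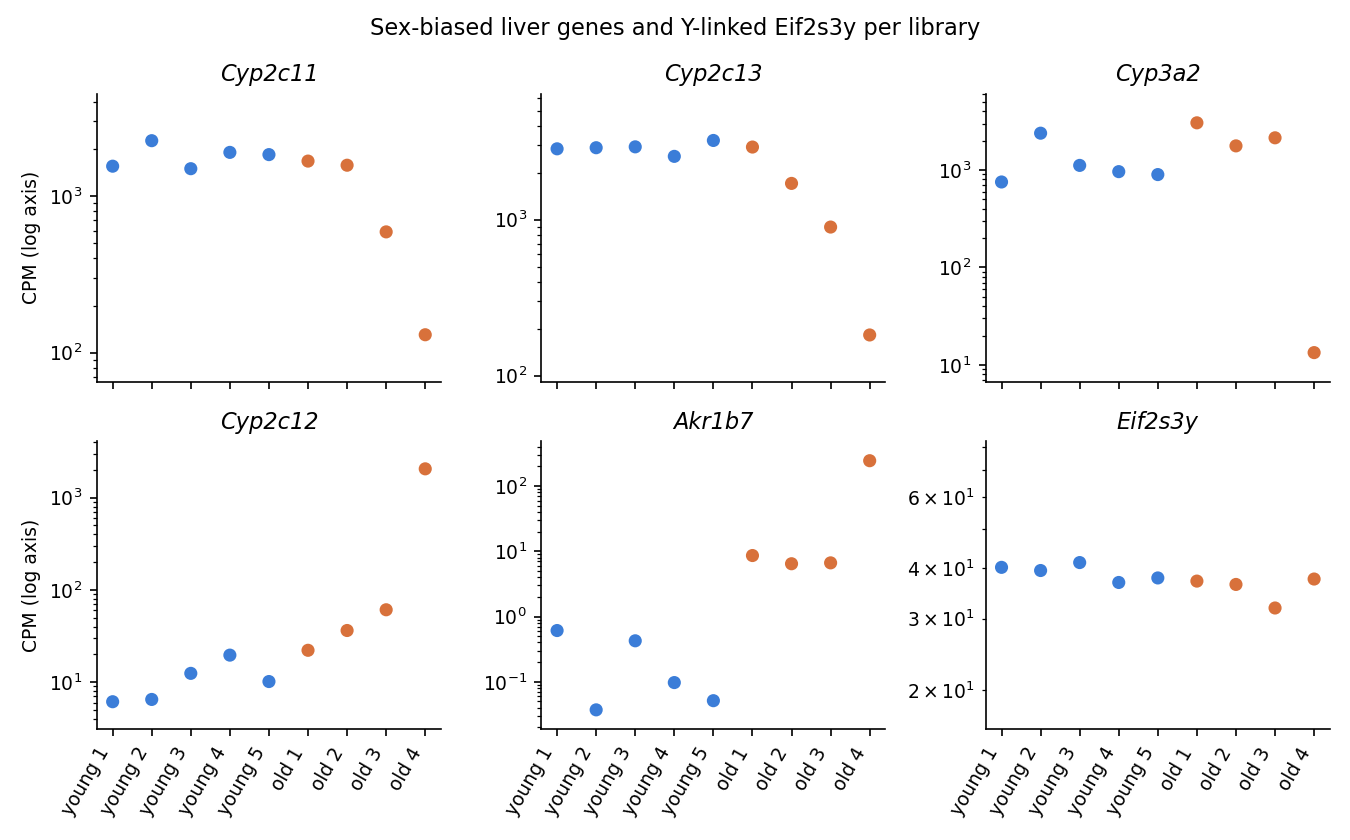
CPM on a log axis (y axis) of the male-biased genes Cyp2c11, Cyp2c13 and Cyp3a2, of Cyp2c12 and Akr1b7, and of the Y-linked gene Eif2s3y, with a point for each of the 5 young and 4 old libraries. Old 4 has 2054 CPM of Cyp2c12 and 130 CPM of Cyp2c11, and 37.6 CPM of Eif2s3y, within the 31.9 to 41.3 CPM of the other libraries.

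Endothelial, matrix and pericentral genes were lower in old livers. The 24 endothelial markers fell with a median of -0.51 (camera adjusted p = 7.65e-06; adjusted p = 0.58 with an estimated correlation), with 1 past and, adjusted over the list alone, 2 lower and 1 higher. Egfl7, a secreted endothelial factor, fell by 0.68, from 8.94 ± 0.449 to 5.58 ± 0.874 CPM (adjusted p = 0.0407; highest 0.103, without young 2). Kdr, the VEGF receptor gene, lay at 84.3 to 101 CPM in young and 32.8 to 83.1 CPM in old livers, and without old 1 the median of the list was -0.30 (adjusted p = 0.000185). The 44 collagen and extracellular matrix genes fell with a median of -0.24, with 0 past by edgeR or adjusted over the list alone, 14 at an unadjusted p under 0.05 and 3 past by DESeq2 (camera adjusted p = 0.00562; adjusted p = 0.72 with an estimated correlation). Without young 3 their median was -0.13 (adjusted p = 0.106), without old 1 their adjusted p was 0.0616, without old 3 their median was -0.38 (adjusted p = 0.00156), and with totals-only scaling it was -0.41 (adjusted p = 0.130). Col1a1 lay at 37.6 CPM in young 3 and at 2.21 to 13.8 CPM elsewhere (adjusted p = 0.278). The 18 pericentral hepatocyte genes fell with a median of -0.31, with 0 past by edgeR over all genes, 6 at an unadjusted p under 0.05, 1 past by DESeq2 and 1 lower when adjusted over the list alone (camera adjusted p = 0.0274; adjusted p = 0.716 with an estimated correlation). That call ended without young 2 (adjusted p = 0.0998), young 5 (0.139), old 1 (0.144) or old 3 (0.159, median -0.12), while without old 4 the median was -0.51, and with totals-only scaling the adjusted p was 0.301. Glul, the pericentral glutamine synthetase gene, lay at 269 ± 127 and 294 ± 77.8 CPM (adjusted p = 0.868).

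Muscle genes were higher in young 2 to 5 than in the other libraries. Young 1 lay near the old libraries, so the lower calls in old livers cannot be read as a change with age. The 4 tested skeletal muscle markers, Mb, Acta1, Ckm and Casq1, were called lower in old as a list (camera adjusted p = 3.39e-04; adjusted p = 0.49 with an estimated correlation), with 1 past the threshold and 3 lower when adjusted over the list alone. Their mean log2 CPM was -2.45 in young 1, 0.62 to 1.07 in young 2 to 5 and -3.09 to -2.51 in the old libraries. The cardiac actin gene Actc1 had 47.2, 40.3, 52.1 and 42.3 CPM in young 2 to 5 and 0 counts in young 1 and in all old libraries. Without 25 heart marker genes the counts were 83 higher and 38 lower. Of the 128 called genes 124 were still tested, and 121 were kept. Muscle genes outside these 25 markers stayed in this fit. It therefore does not show that the remaining lower genes are free of heart transcripts.

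**Figure D4:**
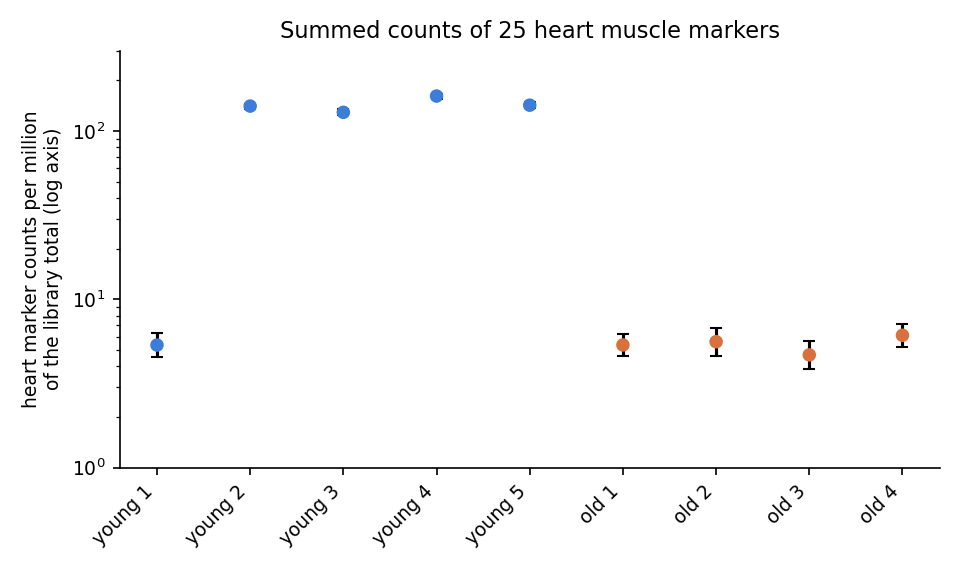
Summed counts of 25 heart muscle marker genes as CPM of the library total, on a log axis (y axis), with Wilson 95% intervals, for each library. Young 2 to 5 lie at 129 to 161, young 1 at 5.34 and the old libraries at 4.67 to 6.11.

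Metabolic lists did not pass as a whole, but single members did. Of 29 glucose metabolism genes 2 fell, Pc, which encodes pyruvate carboxylase (adjusted p = 0.0236; highest 0.0732, without young 4), and G6pc, which encodes glucose-6-phosphatase (adjusted p = 0.0407; highest 0.108, without young 4), and 3 were lower when adjusted over the list alone (list adjusted p = 0.639). The fatty acid transporter gene Cd36 rose by 2.02 (adjusted p = 0.0440; highest 0.122, without young 2) within a lipid droplet and uptake list at 0.917. In the autophagy and lysosome list (0.941), Ctsh, a lysosomal protease gene, fell by 0.65 (adjusted p = 0.0498; highest 0.118, without young 3). Afp, a fetal liver protein gene, rose by 0.99 (adjusted p = 0.0337; highest 0.0977, without young 4) within the preneoplastic and fetal list (0.643), where Gstp1 lay at 16.2 ± 1.74 and 21.4 ± 7.42 CPM. Aqp1, a water channel gene, rose by 1.54 (adjusted p = 0.0391; highest 0.101, without young 2) among cholangiocyte markers (0.683). The stellate cell and fibroblast list had an adjusted p of 0.213. Cish was the passing member of the growth hormone and IGF list (0.169), Cyp2b2 of the xenobiotic P450 list (0.701) and Alb of the periportal list (0.944).

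The remaining metabolic, stress and cell type lists had 0 members past the edgeR threshold over all genes, with 0 to 8 members each at an unadjusted p under 0.05 and 0 to 5 past by DESeq2. Camera adjusted p-values were 0.0836 for nuclear-encoded oxidative phosphorylation, 0.124 for cholesterol synthesis, 0.371 for bile acid synthesis and transport, 0.371 for fatty acid and triglyceride synthesis, 0.681 for fatty acid oxidation and 0.917 for the urea cycle and amino acid catabolism. They were 0.136 for senescence and p53 targets, 0.643 for the cell cycle, 0.643 for NRF2 targets, 0.535 for phase II conjugation, 0.645 for NAD metabolism and 0.974 for heat shock genes. They were 0.371 for plasma cell, 0.377 for mast cell and 0.556 for adipocyte markers. Adjusted over the list alone, 2 heat shock genes were lower, 1 NRF2 target was higher and 1 lower, 1 cholesterol synthesis gene was lower, 1 fatty acid oxidation gene and 1 mast cell marker were higher, and the others of these lists had 0. The bile acid list had a median of 0.01 and a mean of -0.19. Oxidative phosphorylation passed without young 4 (adjusted p = 0.0263), old 3 (1.97e-06, median 0.24) or old 4 (0.0192), but without old 1 it pointed downward (adjusted p = 0.0990, median -0.06) and with totals-only scaling its median was -0.07 (adjusted p = 0.301). Cholesterol synthesis passed without young 2 (0.0436) or old 2 (0.000301), and stellate markers passed without young 3 (0.0320). With totals-only scaling, senescence and p53 targets (0.0265, median -0.01) and cholesterol synthesis (0.0468, median 0.03) passed upward. That is relative to the other genes only, since the median of all genes was -0.17 under this scaling. Without young 2 to 5 together, senescence and p53 targets (0.00422), phase II (0.00589) and cholangiocyte markers (0.0115) passed upward and fatty acid synthesis downward (0.0345). Without old 3 and old 4 together, oxidative phosphorylation (2.90e-12), phase II (0.00975) and NRF2 targets (0.0242) passed upward and fatty acid synthesis downward (0.0195). Without old 3, phase II (0.0386) and urea cycle genes (0.00890) passed, and the cell cycle list passed downward without old 3 (0.0491) and upward without old 4 (0.0192). Of genes fixed for their interest in ageing liver, Rgn lay at 517 ± 83.9 and 439 ± 59.3 CPM (adjusted p = 0.483), Igf1 at 1715 ± 289.8 and 1327 ± 357 CPM (0.388), Cdkn1a at 48.6 ± 28.4 and 86.2 ± 32.4 CPM (0.422) and Mki67 at 2.94 ± 1.10 and 5.30 ± 6.04 CPM (0.533). Cdkn2a had too few counts to be tested, at 0.00742 ± 0.0166 and 0.107 ± 0.0504 CPM.

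For each list with 0 members past by edgeR, limma-voom also called 0, and with quality weights it called 1 acute phase gene and 0 in the other lists. By limma's camera 21 of the 46 lists passed, 16 upward and 5 downward. With an estimated correlation 0 passed and 5 had an unadjusted p under 0.05, and by fry 5 passed (T cell, natural killer, B cell, complement and erythroid lists) and 10 had an unadjusted p under 0.05. With young 1 alone against the old libraries 12 of the 21 lists were kept.

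Old livers differed from each other more than young livers did. The variance of log2 CPM among old animals was 2.45 times that among young animals at the median of 7117 genes, a log2 ratio of 1.29. The permutation p was 0.00794, the smallest that 126 splits can give. Without old 1 the ratio was 1.54 (permutation p = 0.0179, again the smallest possible, with 56 splits). Both p-values are approximate, because the genes were centred on the means of the real groups.

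A few abundant genes took more of the counts in old livers. The 10 most abundant genes held 25.1 ± 1.17% of counts in 5 young and 31.1 ± 3.87% in 4 old libraries (exact permutation p = 0.0159, adjusted 0.0476), and in old 4 the share was 26.3%. The exact permutation p was 0.0571 without young 1, young 2, young 3 or young 5. Alb alone took 10.8 to 11.6% of counts in young and 13.5 to 20.5% in old libraries. Library totals ran from 18942191 to 25215805 counts in young and from 18586798 to 32882704 in old livers (exact permutation p = 0.357, adjusted 0.536), but with old 1 halved the old mean lies below the young mean, at 20726411 against 21674441 counts (exact permutation p = 0.675). In young and old libraries 15812 ± 179 and 15734 ± 351 genes had a count (exact permutation p = 0.690, adjusted 0.690).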

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

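All tests on the heart, female-type and myeloid patterns in this part were chosen after the result was seen. A value is listed where 1 library lay far from the rest of its group relative to the group's range (Dixon's criterion at 95%), which held in 17 of 184 groups of libraries; chance gives about 5%.

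Heart muscle transcripts were found in young 2 to 5, and the markers of muscle stood apart in young 1, where the mean of the skeletal muscle list was -2.45 (log2 CPM) against 0.62 to 1.07 in young 2 to 5 and Myom2 lay at 0.191 CPM against 4.06 to 4.96. An effect of age alone is argued against, since the summed heart markers of young 1 were 0.0414 times the lowest of young 2 to 5, and larger libraries are argued against, since another library had 1.74 times the total of the smallest of them. The heart markers kept about the same proportions in the 4 libraries, with a chi-square of 1.17 per degree of freedom over the 16 of 25 markers that had at most 3 counts in each other library (p = 0.202). This is consistent with a shared source of heart RNA or heart reads, in which Actc1 reached 40.3 to 52.1 CPM, Myh7 12.5 to 14.9 and Myh6 7.69 to 10.2. Whether it entered at dissection, in the library step or in sequencing stays open.

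Old 4 had a female-type set of liver transcripts, with a mean of 8.65 (log2 CPM) over the female-biased genes against 4.56 to 5.18 in the other old libraries. Relative to the other old libraries, its female-biased genes differed by a median of 3.41 and its male-biased genes by -2.84 on the log2 scale. Ces2e, a member of neither sex-biased list, lay at 443 CPM in old 4. It lay at 59.3 to 110 CPM in the other old libraries and at most 4.00 CPM in the young ones. A female animal or female RNA is argued against by the Y-linked gene Eif2s3y, at 37.6 CPM within the 31.9 to 41.3 CPM of the other 8 libraries. A general loss of hepatocyte transcripts is argued against by the hepatocyte markers, which differed by a median of -0.25. The age of this animal, its hormonal state and its health may each be involved and were not tested.

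Old 3 had high myeloid transcripts, with a mean of 3.81 (log2 CPM) over the monocyte and neutrophil markers against 0.52 to 0.96 in the other old libraries. More residual blood of the makeup seen in old 4 stays open. Over lists fixed in advance, 10 tested monocyte and neutrophil markers exceeded old 4 by a median ratio of 6.09 (1.64 to 61.2) and 7 tested erythroid markers by 2.05 (1.70 to 6.56; exact rank-sum p = 0.0185). Over all members with at least 3 counts in either library, tested or not, the medians were 7.59 for 17 myeloid and 3.89 for 12 erythroid markers (exact rank-sum p = 0.0725), with counts under 3 set to that floor. In old 3 S100a9 lay at 76.1, S100a8 at 43.4 and Mpo, a gene of myeloid precursors, at 30.4 CPM, and Mki67, a gene of dividing cells, lay at 14.3 CPM against 1.40 to 3.11 in the other old libraries. The stage of these cells was not tested. Myeloid cells in this liver are another candidate source, and the age of the animal stays open, as untested.

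Mb lay at 0.0705 CPM in old 1 and at 0 counts in the other old libraries. Tex13b lay at 9.28 CPM in old 3 and at 7.82 to 7.83 in the other old libraries. Slc14a1 lay at 0.0486 CPM in young 4 and at 0.186 to 0.205 in the other young libraries. Scrn1 lay at 17.3 CPM in young 3, where the young mean was 7.24. Isg15 lay at 4.26 CPM in young 5 against 3.34 to 3.60. Aqp1 lay at 8.84 CPM in young 1 against 14.0 to 15.5. Rgn lay at 370.1 CPM in young 4 against 529 to 572 in the other young libraries, and at 350.2 in old 3 against 464 to 473 in the other old ones. Cdkn2a lay at 0.0371 CPM in young 2 and had 0 counts in the other young libraries. The flagged values of Mb, Slc14a1 and Cdkn2a lie under the 3-count floor of their libraries. That floor is 0.106 CPM in old 1, 0.146 in young 4 and 0.111 in young 2. These values cannot be told apart from counting error. Col1a1 lay at 37.6 CPM in young 3 against 4.27 to 13.8. The mean of the complement and coagulation list was 8.68 (log2 CPM) in young 1 against 8.57 to 8.60 in the other young libraries.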

How the results depend on the processing

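The fits with old 1 halved, without old 3 and 4 together, without young 2 to 5 together, without heart marker genes, and the list tests under totals-only and upper-quartile scaling were chosen after seeing the data. Of the counts of genes and lists and the measure of spread, 63 alternative values stayed within the bounds of the reported result, 32 were weaker and 6 stronger. Of single genes, lists and library measures, 1526 stayed, 346 were weaker, 20 stronger and 2 that had passed turned direction; a value not past the threshold in either fit counts as stayed, whatever its sign. In all these fits the called genes that were tested kept their sign.

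The 84 higher, 44 lower and 89 at least 2-fold changed genes became 386, 269 and 302 with DESeq2 (all 128 called genes included), 35, 26 and 44 with limma-voom, and 44, 14 and 44 with quality weights. With totals-only scaling 208 were lower. Leaving out each library gave 20 to 115 higher, 10 to 86 lower and 26 to 157 changed 2-fold, lowest without young 4 and highest without old 2. Without old 3 and 4 together 26 were lower, and 43 of the 128 genes were kept. Without young 2 to 5 together edgeR called 0 higher, 0 lower and 0 changed 2-fold, with 429 at an unadjusted p under 0.05 and no other tool run; fewer libraries were fitted there. For the other changes the cause was not tested.

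Of the 21 lists past the threshold, 0 passed with an estimated correlation (5 at an unadjusted p under 0.05) and 5 with fry. The Kupffer cell and macrophage list turned direction without old 3 and 4 together (median log2 -0.15, adjusted p = 0.712) and without young 2 to 5 together (median 0.28, with the camera test downward, adjusted p = 0.884). The variance ratio of old to young stayed past the threshold in every fit, with a log2 ratio of 0.62 to 1.43 when a library was left out and 1.23 to 1.37 with other expression limits.

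With the replicate number as a block (a replicate block) 27 genes were higher, 16 lower and 41 changed 2-fold, 30 of the 128 genes were kept, and 19 of 21 lists passed, without the unfolded protein response (0.150) and pericentral (0.197) lists. The numbers were not taken to pair the animals: deviations of same-numbered libraries correlated at -0.098, 0.096, 0.315 and -0.167, and the best partners of old 1 to 4 were young 4, 5, 3 and 1. In 100 drawn of the 126 splits of the libraries into 4 and 5, only 1, the real split, gave 128 genes or more, a share of 0.01. The highest other split gave 27 and set young 2 to 5, which hold heart transcripts, against the rest. The real split also sets young 2 to 5 against the old libraries. Counting splits therefore cannot separate age from whatever else set these young libraries apart. This test was set beforehand. Depth limits genes under about 3 counts in a library, such as Cdkn2a.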

Other observations

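The circadian clock list and its test were fixed in advance. The single genes in this part were chosen after their values were seen, and no further test was made on them. Of 15 circadian clock genes 0 passed edgeR's test over all genes, with 6 at an unadjusted p under 0.05 and 4 past by DESeq2, and 2 were higher and 4 lower when adjusted over the list alone, while the list as a whole was not past the threshold (camera adjusted p = 0.402). The log2 fold changes were -1.85 for Dbp, -1.08 for Nr1d1, -0.78 for Nr1d2, -1.39 for Per3, 0.46 for Npas2 and 0.88 for Nfil3. The time of day of tissue collection was not given in the sources used here.

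Some genes were nearly absent at 1 age and present at the other. Caln1, a calcium-binding protein gene, lay at 3.68 to 6.90 CPM in old and 0.146 to 0.800 CPM in young livers, and RGD1560961 at 1.20 to 1.69 against 0.0472 to 0.146 CPM. In the other direction, RGD1562420 lay at 6.29 to 10.7 CPM in young livers and at most 0.141 CPM in old ones, RGD1564801 at 1.54 to 4.25 against at most 0.0705 CPM, and LOC687532 at 5.90 to 11.2 against at most 1.08 CPM. These genes kept their call whichever library was left out, with edgeR adjusted p-values of at most 0.0297.

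Some single genes outside the lists were past the threshold. Sp140, a nuclear body gene of leukocytes, rose from 3.81 ± 0.457 CPM (n = 5) to 8.84 ± 0.945 CPM (n = 4; edgeR adjusted p = 0.00670), and RT1-CE14, a class I gene uncertain within its family, from 5.52 ± 1.38 to 15.2 ± 1.87 CPM (adjusted p = 0.00829). Il2rb, an interleukin receptor gene of T and natural killer cells, rose by 0.98 (adjusted p = 0.0372; highest 0.0911, without young 5). Bpgm, a glycolytic gene abundant in red cells, rose by 1.07 (adjusted p = 0.0389; highest 0.107, without young 4). Among secreted liver proteins, Hrg rose by 0.89 (adjusted p = 0.0332; highest 0.0972, without young 4). The carboxylesterase gene Ces2g, uncertain because of close paralogs, fell by 0.87, from 38.8 ± 5.22 to 21.2 ± 1.55 CPM (adjusted p = 0.00840).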
